A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

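Saccharomyces cerevisiae BY4741 was grown on glucose, moved to solid acetate medium on nylon membranes and exposed to N2 or CO for 15, 30, 45, 60 or 120 min or for 24 h, per the labels. RNA of exposed cells (Cy5) and of cells kept in room air for the same time (Cy3) was hybridised to 1 array per gas and time, which gave 12 arrays. The values were used as deposited: a table of log2 ratios of the channels, 1 per ORF and array, given to 2 decimals, as calculated by the authors. The base of the logarithm, the direction of the ratio, the background correction and any normalization or centring are not given in the sources used here. Base 2 was assumed from the range of the values, and the direction was taken as gas over air from the dyes. The higher values of OLE1, COX5B and TIR1, known hypoxic genes, fit this direction, while the low HEM13 and the near-zero DAN1 do not follow it. The platform, its probe sequences, the signal over background and whether both gases shared an air reference at a given time are not given in the sources used here either. An ORF with close relatives elsewhere in the genome, such as a Ty element, a paralogous ribosomal protein gene, a seripauperin, HXT6 and HXT7, or CCW12 and CCW22, can therefore carry signal from its relatives.

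Of the 6150 ORFs in the table, the 5672 with a value on all 12 arrays were tested. ORF names were matched to the locus tags of an annotation, R64, used for symbols and neighbours alone; 5651 ORFs matched, 499 did not and are given by their ORF name, and 5358 of those tested were matched. Coordinates are not printed, since the build behind the array is not given in the sources used here.

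Each ORF was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 5672 ORFs and a threshold of 0.05. N2 and CO were each compared with air as the mean of 6 log2 ratios against 0, in a fit of group means with 10 residual degrees of freedom. CO was compared with N2 with time as a block (5 residual degrees of freedom), because the labels give both gases the same 6 times and air cells of the corresponding time; the gases' deviations from their own means correlated across ORFs at r of 0.255 to 0.776 at matching times. At 30 and 45 min the CO array correlated more closely with an N2 array of another time (r = 0.571 and 0.385), so the pairing rests on the labels. Without that block 0 ORFs were called, the same number as with it. The 24 h arrays were compared with the equal-weight mean of 3 earlier periods (15 and 30, 45, and 60 and 120 min), and 60 and 120 min with 15 and 30 min, in a fit with period and gas (7 residual degrees of freedom). Arrays of different times are not true replicates, so each p measures a change against the spread between these arrays and not between cultures. A constant dye effect cancels in the last 3 comparisons and does not cancel in the ratios to air.

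A set of 40 gene lists was fixed with the tests, the gene-naming rule and the alternative settings before the data were examined. The 39 lists with at least 4 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01 in each of the 5 comparisons, and the 195 tests were adjusted together; the list of mitochondrially encoded genes had 0 members in the table. With an estimated correlation 0 of the 53 list calls held. Counts adjusted over the list alone used Benjamini-Hochberg over a list's own genes. The exact sign-flip test over the 6 times was two-sided, and the smallest p it allows is 0.0312.

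Genes named for the ratios to air were up to 10 with the highest and 10 with the lowest mean among those called in both gases with 1 sign on all 12 arrays. For CO against N2 they were up to 8 in each direction with 1 sign at all 6 times, which no gene met. For 24 h they were up to 8 in each direction outside the range of the 5 earlier times in both gases, and for 60 and 120 min up to 8 in each direction with 1 sign in both gases. Up to 4 members were named from each list described, along with fixed regulators, hypoxic genes, heme proteins and the genes that the strain lacks; CYC1 is not reported, since it had a value on 10 arrays. OST2 and members of lists without a call were chosen after their values were seen.

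The fits were tested on simulated data built from the residual spread, with 200 genes changed by a log2 of 1 or 2. Of the genes changed by 1, 87% were recovered for N2, 84% for CO, 87% for CO against N2, 71% for 24 h and 80% for 60 and 120 min, and 9 to 16 of 5452 unchanged genes were called. The simulated noise was independent between genes and between arrays, which the real noise need not be. These rates therefore describe the fits and not the power or the false calls in these data. The overlap of the gases was set against 20 simulated pairs of gases without any change that shared an air reference.

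Alternatives tried were centring each array on its median, quantile normalization between arrays, ORFs with values on at least 10 arrays, ORFs with an absolute log2 ratio of at least 0.5 on at least 2 arrays, robust eBayes, array weights, other block structures, and leaving out each time and each array. For lists they were camera with an estimated correlation, fry, median centring and leaving out 24 h. Subtraction of each gas's 15 min ratios was chosen after seeing the data, as was the swap of the gases within times over all lists, which took the largest absolute list mean of each swap. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.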

Results

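Transcript levels were measured on 12 2-colour arrays in Saccharomyces cerevisiae BY4741, a haploid laboratory strain that lacks HIS3, LEU2, MET17 and URA3 in whole or part. The cells respired acetate on plates and were moved from room air into pure nitrogen (N2), which removes oxygen, or into carbon monoxide (CO), which removes oxygen and also binds reduced heme. Each gas had 6 arrays, taken after 15, 30, 45, 60 and 120 min and after 24 h, with 1 array per gas and time. Every array set RNA from gas-exposed cells in the Cy5 channel against RNA from air-exposed cells of the same time in the Cy3 channel. There were no replicate arrays of a gas and time and no dye swap, so the 6 times stood in for replicates and the errors given here are spreads between times. The number of arrays limits the precision.

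The table held 6150 open reading frames (ORFs), of which 5843 to 6056 had a value on a given array and 5672 on all 12. Values are given as log2 of gas over air, where the base and the direction were taken from the range of the values and from the dyes, because the labels state neither. The median log2 ratio was 0.00, 0.00, 0.00, -0.04, -0.06 and -0.18 in CO from 15 min to 24 h, and 0.01, 0.00, -0.03, -0.02, 0.00 and -0.03 in N2. The SD of the ratios across genes widened from 0.342 at 15 min to 1.19 at 24 h in CO and from 0.337 to 1.28 in N2. At 15 min 39 ORFs were at least 2-fold higher in CO and 28 lower, against 913 and 1210 at 24 h. In N2 these counts were 58 and 21 at 15 min and 1129 and 1175 at 24 h. The genes missing from the strain in whole or part served as a background, though a gene missing only in part can still carry signal of its own. HIS3 (YOR202W), LEU2 (YCL018W), MET17 (YLR303W) and URA3 (YEL021W) had 48 values between -0.91 and 0.67, with an SD of 0.317. As a list of 4 they passed no test in any comparison, with a mean of -0.16 in N2 (adjusted p = 0.579) and -0.11 in CO (adjusted p = 0.738). With the 15 min ratios subtracted, URA3 was called in N2 at -0.69 (adjusted p = 0.00934), and with exposure time as a block LEU2 was at -0.29 (adjusted p = 0.044).

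The ratios of each gas to air ask how respiring cells change their transcripts when oxygen is withdrawn, and whether CO has an effect like that of anoxia. In both gases the lists of ribosome biogenesis and ribosomal protein genes shifted downward, and those of seripauperins, storage carbohydrates and hypoxic genes upward through part of their members. These lists passed with a preset correlation and none with an estimated one (adjusted p = 0.63 to 0.797 with an estimated correlation). UTP6 (YDR449C), a component of the complex that processes the small-subunit rRNA, fell by 2.09 ± 0.33 (log2, SE, n = 6 arrays) in N2 and by 2.06 ± 0.33 in CO. SPI1 (YER150W), a cell wall protein of stationary-phase cells, rose by 2.28 ± 0.49 in N2 (adjusted p = 0.00361) and by 1.67 ± 0.49 in CO (adjusted p = 0.0189). ERG11 (YHR007C), the heme enzyme that demethylates lanosterol, stood at -2.00 ± 0.28 in N2 and -1.83 ± 0.28 in CO, and fell in both. Over all genes 1001 were called higher and 1146 lower in N2, and 720 higher and 1098 lower in CO; 220 and 302 of those in N2, and 128 and 322 of those in CO, moved at least 2-fold. The CO call of SPI1 was lost without 45, 60 or 120 min or the CO array of 24 h (highest adjusted p = 0.0669). The count in N2 fell from 2147 to 1370 without 45 min, and that in CO from 1818 to 1052 without 60 min, to 1042 without 120 min and to 1141 without the CO array of 120 min. With exposure time as a block, which leaves the spread between times that the gases share out of the error, 1597 were higher and 1740 lower in N2 and 1441 and 1727 in CO.

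Ribosome biogenesis factors gave the smallest list p in both gases. Of 76 measured members, 64 fell and 0 rose in N2 (64 adjusted over the list alone) and 56 fell in CO (64 adjusted over the list alone). The list test gave adjusted p = 7.87e-16 in N2 and 4.45e-17 in CO, and adjusted p = 0.63 with an estimated correlation in both. Examples besides UTP6 were UTP13 (YLR222C), at -1.75 ± 0.31 in N2 and -1.88 ± 0.31 in CO, and NOP56 (YLR197W), a core protein of small nucleolar RNPs, at -1.70 ± 0.28 in N2. Of 120 cytosolic ribosomal protein genes, 67 fell in N2 and 64 in CO (70 and 72 adjusted over the list alone), with adjusted p = 7.64e-11 and 3.25e-09, and adjusted p = 0.797 with an estimated correlation in both. RPS0B (YLR048W) fell by 1.94 ± 0.43 in N2 and by 1.72 ± 0.43 in CO, and RPL7B (YPL198W) fell by 1.83 ± 0.36 in CO. The exception was RPL4B (YDR012W), which rose by 0.65 ± 0.18 in CO, a call lost without the CO array of 60 min (adjusted p = 0.056). Many of these genes exist as near-identical pairs, which probes of unknown sequence cannot be assumed to tell apart. Subunits of RNA polymerases I and III fell in 9 of 18 cases in N2 and 13 in CO (12 and 14 adjusted over the list alone, with 0 and 1 higher). The list had adjusted p = 0.00112 and 9.95e-05, and adjusted p = 0.63 with an estimated correlation in both gases. RPA49 (YNL248C), a polymerase I subunit, fell by 1.79 ± 0.24 in N2 and by 2.16 ± 0.24 in CO.

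Among the classic hypoxic genes of respiration and membrane, 6 of 9 rose in N2 and 3 in CO, where 1 fell; adjusted over the list alone, 6 rose and 1 fell in each gas. The list passed in N2 (adjusted p = 0.0263) and CO (adjusted p = 0.0231), with adjusted p = 0.63 with an estimated correlation, and was lost without 24 h (adjusted p = 0.0889 and 0.0629). SUT1 (YGL162W), a regulator of sterol uptake, rose by 1.62 ± 0.20 in N2 and by 1.81 ± 0.20 in CO, and FET4 (YMR319C), a low-affinity iron transporter, rose by 1.22 ± 0.21 and 1.12 ± 0.21. OLE1 (YGL055W), the oxygen-requiring fatty acid desaturase, rose by 1.49 ± 0.35 in N2 and stood at 0.84 ± 0.35 in CO (adjusted p = 0.0807). COX5B (YIL111W), the hypoxic isoform of cytochrome oxidase subunit V, rose by 1.03 ± 0.34 in N2 (adjusted p = 0.0289, and up to 0.0979 without 60 or 120 min or the N2 array of 24 h) and stood at 0.90 ± 0.34 in CO (adjusted p = 0.0545). CYC7 (YEL039C), the hypoxic cytochrome c, rose by 1.10 ± 0.32 in N2, a call lost without 60 or 120 min or the N2 array of 24 h (highest adjusted p = 0.0751), and by 1.23 ± 0.32 in CO. HEM13 (YDR044W), a heme synthesis enzyme known for its induction under hypoxia, instead fell by 0.82 ± 0.21 in CO (adjusted p = 0.0101, but 0.055 without 60 min) and stood at -0.53 ± 0.21 in N2 (adjusted p = 0.0598). The calls of SUT1 (adjusted p = 0.488 in N2 and 0.0631 in CO) and FET4 (adjusted p = 0.278 and 0.397) were lost with the 15 min ratios subtracted. ANB1 (YJR047C), COX5A (YNL052W) and the activator genes HAP4 (YKL109W) and UPC2 (YDR213W) passed in neither gas. For HAP4 the mean joins opposite values. It stood between -0.53 and -1.28 in both gases from 15 to 60 min, and at 1.79 in CO and 2.03 in N2 at 24 h. With exposure time as a block OLE1, COX5B and COX5A passed in CO (adjusted p = 0.00137, 7.48e-05 and 0.0406) and HEM13 and HMG1 (YML075C) in N2 (adjusted p = 0.00152 and 0.044).

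Anaerobic cell wall genes moved in part. Of the seripauperins, a subtelomeric family of cell wall proteins with closely similar sequences, 12 of 18 rose in N2 (13 adjusted over the list alone) and 5 in CO (4 adjusted over the list alone). The list had adjusted p = 2.3e-05 in N2, with adjusted p = 0.63 with an estimated correlation, and adjusted p = 0.0231 in CO, with adjusted p = 0.79 with an estimated correlation. Its CO mean of 0.27 was 0.15 without 120 min, where it was lost (adjusted p = 0.166). PAU5 (YFL020C) rose by 1.05 ± 0.17 in N2 and by 0.67 ± 0.17 in CO. Of 4 measured anaerobic mannoproteins 2 rose in each gas, TIR1 (YER011W) by 0.92 ± 0.16 in N2 and 0.71 ± 0.16 in CO and TIR2 (YOR010C) by 1.18 ± 0.27 and 0.86 ± 0.27, while DAN1 (YJR150C) stood at 0.15 ± 0.11 and -0.08 ± 0.11; the list did not pass (adjusted p = 0.0884 and 0.352). The CO call of TIR2 was lost without 60 or 120 min or the CO array of 24 h (highest adjusted p = 0.0966). ROX1 (YPR065W), the repressor of hypoxic genes, fell by 0.66 in N2 and by 0.44 in CO (adjusted p = 0.0394, a call lost without any of 30 min to 24 h, highest adjusted p = 0.133). MOT3 (YMR070W), another repressor, fell by 0.79 in N2 and stood at -0.41 in CO (adjusted p = 0.135). HAP1 (YLR256W), the heme-responsive activator, fell by 0.42 in N2 and 0.54 in CO, and the sterol regulator ECM22 (YLR228C) rose by 0.50 and 0.65, but each of these 4 calls was lost without at least 1 time (adjusted p up to 0.154, 0.0668, 0.126 and 0.0528, each among 30 min to 24 h). The N2 call of HAP1 was also lost with median centring, quantile normalization, array weights or the N2 arrays alone (adjusted p up to 0.105). The CO call of ROX1 was also lost with median centring or the CO arrays alone (adjusted p = 0.057 and 0.0563).

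Lists of stored carbohydrate, oxidative defence and iron genes shifted upward in both gases and that of general stress in N2, each through part of its members. Of 18 trehalose and glycogen genes, 8 rose and 1 fell in N2 (8 and 1 adjusted over the list alone), and 7 rose and 1 fell in CO (9 and 1 adjusted over the list alone). The list had adjusted p = 0.00647 and 0.00169, and adjusted p = 0.63 with an estimated correlation. GSY2 (YLR258W), glycogen synthase, rose by 1.06 ± 0.33 in N2 (lost without 60 or 120 min or the N2 array of 24 h, adjusted p up to 0.0849) and 1.42 ± 0.33 in CO, and GLC3 (YEL011W), the branching enzyme, by 1.13 ± 0.22 and 1.34 ± 0.22. General stress genes rose in 9 of 17 cases in N2 with 1 lower, also adjusted over the list alone (adjusted p = 0.0127, adjusted p = 0.63 with an estimated correlation), while in CO the list missed the threshold (adjusted p = 0.0661) but passed without 24 h (adjusted p = 0.0474). GRE2 (YOL151W), a reductase, rose by 1.53 ± 0.24 in N2 and 1.55 ± 0.24 in CO, and GPP2 (YER062C), which makes glycerol, fell by 1.15 ± 0.24 and 1.46 ± 0.24. Of 17 oxidative defence genes 7 rose in each gas, also adjusted over the list alone, OYE3 (YPL171C), an NADPH oxidoreductase, by 0.98 ± 0.18 in N2 and 0.85 ± 0.18 in CO. That list had adjusted p = 0.0494 and 0.0238, with adjusted p = 0.63 with an estimated correlation, and was lost without 45 min, 60 min or 24 h in N2 (up to adjusted p = 0.104) and without 24 h in CO (adjusted p = 0.0545).

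Iron uptake genes split: of 23, 12 rose and 2 fell in N2 and 9 rose and 2 fell in CO (14 and 2, and 10 and 2, adjusted over the list alone), with adjusted p = 0.01 and 0.0259 and adjusted p = 0.64 with an estimated correlation. FIT3 (YOR383C), a siderophore-binding cell wall protein, rose by 1.68 ± 0.49 in N2 and 1.54 ± 0.49 in CO (lost without 60 or 120 min or the CO array of 24 h, adjusted p up to 0.104), and ISU1 (YPL135W), the iron-sulfur scaffold, by 1.53 ± 0.37 and 1.80 ± 0.37. FTR1 (YER145C) and CCC2 (YDR270W), the permease and the copper pump of high-affinity uptake, which works with an oxygen-consuming oxidase, fell by 1.37 ± 0.30 and 1.02 ± 0.21 in N2 and by 1.35 ± 0.30 and 1.22 ± 0.21 in CO. With the 15 min ratios subtracted the calls of FTR1 (adjusted p = 0.659 in N2 and 0.236 in CO) and CCC2 (adjusted p = 0.139 and 0.624) were lost. Of 24 ergosterol genes 10 fell and 2 rose in N2 (12 and 3 adjusted over the list alone). As a list they had adjusted p = 0.0415 and adjusted p = 0.64 with an estimated correlation. Without 60 or 120 min the list was lost (adjusted p up to 0.0718). In CO 6 fell and 2 rose and the list did not pass (adjusted p = 0.142). ERG25 (YGR060W) fell by 1.94 ± 0.40 in N2 and ERG1 (YGR175C) by 1.56 ± 0.41, both enzymes that use oxygen. HMG2 (YLR450W), the hypoxic isozyme of HMG-CoA reductase, rose by 0.65 in N2 and stood at 0.16 in CO; its call was lost without 45 or 120 min (highest adjusted p = 0.0775). HMG1 (YML075C), the aerobic isozyme, stood at -0.32 in N2 and fell by 0.65 in CO, lost without 60 or 120 min or the CO array of 24 h (highest adjusted p = 0.071). Fatty acid genes rose in 4 of 10 cases in N2 (5 adjusted over the list alone). Tested together they gave adjusted p = 0.0481 and adjusted p = 0.64 with an estimated correlation. Without 45, 60 or 120 min or 24 h the list was lost (adjusted p up to 0.0848).

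Of the respiratory lists, that of cytochrome c and complexes III and IV and that of ATP synthase passed against air in CO, where in N2 they had adjusted p = 0.386 and 0.646. The NADH and succinate dehydrogenases (adjusted p = 0.681 in both gases) and the TCA cycle (adjusted p = 0.0947 in N2, or 0.0178 without 24 h, and 0.891 in CO) did not pass. Of 14 genes of cytochrome c and complexes III and IV, 4 rose in CO (4 adjusted over the list alone), among them QCR8 (YJL166W) by 1.28 ± 0.24. Their list passed at adjusted p = 0.00998 and adjusted p = 0.649 with an estimated correlation. Without 24 h the list was lost (adjusted p = 0.0649). Of 15 ATP synthase genes 2 rose (2 adjusted over the list alone), ATP5 (YDR298C) by 0.84 ± 0.17; that list was lost without any time but 120 min (highest adjusted p = 0.138), without which its mean of 0.33 was 0.54. For this list limma gave adjusted p = 0.0498 and adjusted p = 0.797 with an estimated correlation. Genes of daughter cell separation were higher in both gases through 2 of 10 members, also adjusted over the list alone: CTS1 (YLR286C), the chitinase that parts mother and daughter, rose by 1.57 ± 0.28 in N2 and 1.28 ± 0.28 in CO, and SIC1 (YLR079W), an inhibitor of cyclin-dependent kinase, by 1.00 ± 0.15 and 0.70 ± 0.15. The list had adjusted p = 0.0413 and 0.0451, with adjusted p = 0.753 with an estimated correlation, and was lost without 24 h in N2 (adjusted p = 0.0668) and without 120 min in CO (adjusted p = 0.0551). The 24 h arrays carried much of its mean, which without them was 0.36 in N2 instead of 0.74 and 0.36 in CO instead of 0.61.

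A single set of genes carried most of both responses. Of the genes called, 567 were higher in both gases, where 127 would be if the calls of the gases were independent. Lower in both were 859, where 222 would be. The calls are not independent, since both gases share 1 estimate of the spread per gene and may share air references. Of these 1426 genes 0 had opposite signs. Mean ratios in the gases correlated across genes with r = 0.912, against 0.501 in simulated unchanged genes whose gases shared an air reference; genes are not independent replicates. Of the 1426, 449 were higher and 632 lower on all 12 arrays. The farthest of these upward, besides SPI1, were ICY1 (YMR195W), at 2.20 ± 0.26 in N2 and 1.90 ± 0.26 in CO, and SPG1 (YGR236C), a gene needed in stationary phase, at 1.97 ± 0.36 and 1.96 ± 0.36. The wall proteins SCW4 (YGR279C) and CCW12 (YLR110C) rose by 2.05 ± 0.66 and 1.91 ± 0.45 in N2 and by 1.84 ± 0.66 and 1.65 ± 0.45 in CO, and BDH2 (YAL061W), a putative alcohol dehydrogenase, by 1.48 ± 0.24 and 2.03 ± 0.24. Ty1 retrotransposon ORFs YER138C and YJR027W rose by 1.97 ± 0.49 and 1.92 ± 0.46 in N2 and by 1.60 ± 0.49 and 1.61 ± 0.46 in CO, and ORFs YMR046W-A and YER138W-A by 1.95 ± 0.47 and 1.88 ± 0.59 in N2 and 1.72 ± 0.47 and 1.90 ± 0.59 in CO. The farthest downward, besides UTP6, RPA49 and ERG11, included HOM3 (YER052C), aspartate kinase, at -2.16 ± 0.34 and -2.37 ± 0.34, and ILV5 (YLR355C), a branched-chain amino acid enzyme, at -1.93 ± 0.31 and -2.31 ± 0.31. YOL079W, YRO2 (YBR054W), ANK1 (YGL242C), SEC63 (YOR254C), a protein of import into the endoplasmic reticulum, and TMN3 (YER113C) fell to -2.10, -1.94, -2.22, -2.03 and -1.84 in N2 and to -2.31, -2.30, -1.81, -1.90 and -1.98 in CO. With a time or an array left out, the N2 calls of SCW4 (45 or 120 min, or the N2 array of 24 h) and YER138W-A (45, 60 or 120 min, or the N2 array of 24 h) were lost, with adjusted p up to 0.0918 and 0.0818. The CO calls of CCW12, YJR027W, YMR046W-A, YER138C, YER138W-A and SCW4 were each lost without 120 min, with adjusted p up to 0.0626, 0.064, 0.0539, 0.0779, 0.0871 and 0.166. That of YER138C was also lost without 45 min, that of YER138W-A without 60 min and that of SCW4 without 45 or 60 min or the N2 array of 30 min, and those of all but CCW12 without the CO array of 24 h. Since the dyes were never swapped, a constant labelling bias cannot be separated from a gene's mean ratio. With the 15 min ratios subtracted, which cancels it, 354 genes were higher and 676 lower in N2, and 346 and 761 in CO. These counts rest on 1 array of 15 min per gas. Its noise is shared by all later arrays of that gas and is left out of the error, so the p-values can be too small. The subtraction also removes any change made by 15 min, and 63 of 148 gene calls named or drawn from the lists were lost with it. Of these 63, 46 had a log2 more than 1.5 times smaller, as the ORF YER138C did in N2 (0.23), or of the other sign. Those of the other sign were MRS4 in N2 (-0.046) and RPL4B in CO (-0.002). The other 17 kept their log2 within 1.5 times and missed the threshold. Among those named, the log2 shrank by more than 1.5 times in N2 for ICY1, SPG1, BDH2, the ORFs YER138C, YJR027W, YMR046W-A and YER138W-A, ROX1, SUT1, FET4, GRE2, FTR1, CCC2 and YHB1. In CO it did so for CCW12, BDH2, the same ORFs, ANK1, TIR1, PAU5, SUT1, FET4, OYE3, GRE2, CTS1, SIC1, FTR1 and CCC2. It stayed within 1.5 times in N2 for SCW4 (1.99), MOT3 (-0.64), HMG2 (0.66), CTT1 (0.53), ERG1 (-1.06), GSY2 (0.88) and FIT3 (1.30), with adjusted p of 0.05 to 0.109. In CO it stayed so for SPI1 (1.29), SCW4 (2.12), ROX1 (-0.44), ATP5 (0.57), FIT3 (1.27) and TIR2 (0.69), with adjusted p of 0.0534 to 0.11.

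**Figure D1:**
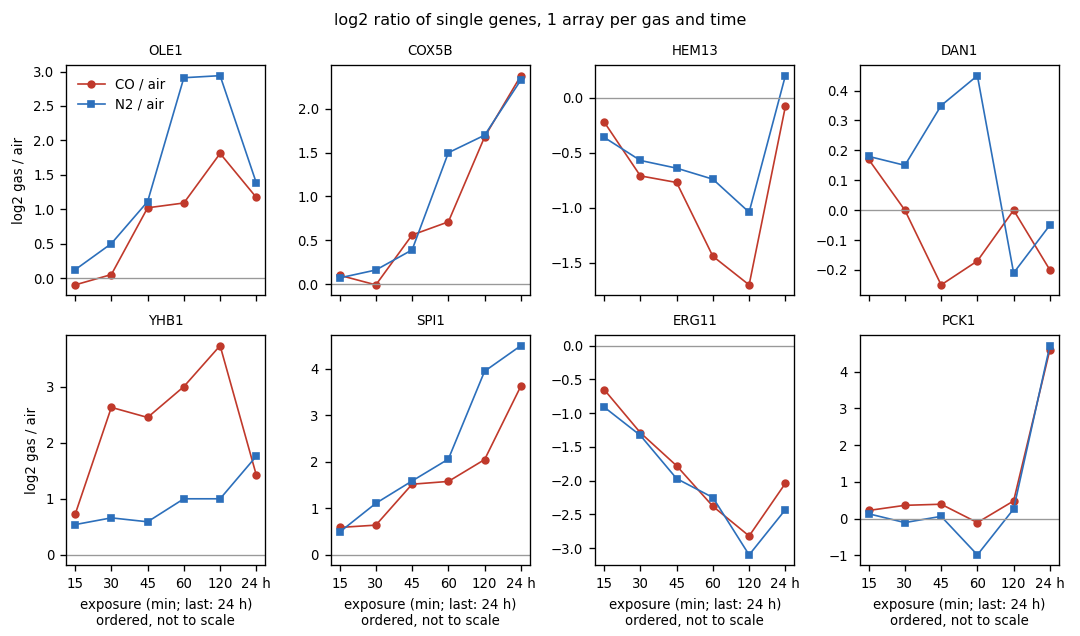
Log2 ratio of gas over air (y axis, its own range in each panel) on each array for 8 genes by exposure time (x axis), with 1 point per array for CO and for N2. OLE1 and YHB1 lie apart between the gases over part of the course, and PCK1 is far higher at 24 h than at any earlier time.

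The difference between the gases asks which transcripts respond to CO beyond the loss of oxygen, with each CO array paired with the N2 array of its time. Genes of the TCA cycle, which oxidises acetate, were higher in CO than in N2 by a mean of 0.35 ± 0.26 (log2, SD across n = 6 times, CO higher at 6 of 6). The list passed with a preset correlation (adjusted p = 2.5e-06) and not with an estimated one (adjusted p = 0.63 with an estimated correlation), and 0 of 13 genes passed over all genes. FUM1 (YPL262W), fumarase, stood 0.76 ± 0.16 higher in CO, LPD1 (YFL018C), a dehydrogenase subunit, 0.54 ± 0.17 and LSC2 (YGR244C), a succinyl-CoA ligase subunit, 0.51 ± 0.12 (adjusted p = 0.323, 0.374 and 0.374). YHB1 (YGR234W), a flavohemoglobin that consumes nitric oxide, was 1.40 ± 0.36 higher in CO (adjusted p = 0.374); it rose by 2.33 ± 0.30 against air in CO and by 0.93 ± 0.30 in N2, the latter lost without 30, 45 or 60 min, 24 h or the N2 array of 120 min (highest adjusted p = 0.0868). Its difference was 0.18 at 15 min, between 1.86 and 2.73 from 30 to 120 min, and -0.34 at 24 h. CTT1 (YGR088W), the cytosolic catalase, a heme enzyme, was lower in CO at 6 of 6 times, by a mean of -0.71 ± 0.18 (adjusted p = 0.374), having risen by 0.63 ± 0.17 against air in N2 (lost without 45 min, adjusted p = 0.0503) and stood at -0.08 ± 0.17 in CO.

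Over all genes limma called 0 of 5672 different between the gases, with 584 at an unadjusted p under 0.05 where chance gives 284. The smallest adjusted p was 0.0522, for OST2 (YOR103C), a subunit of oligosaccharyltransferase, which was -1.45 ± 0.18 in CO relative to N2 and lower at 6 of 6 times; it was picked out after its values were seen, and was called when arrays were centred on their medians, when little-changing genes were left out, or when time was a random block (1 gene each). Without the time pairing 0 genes were called.

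Of the 39 lists tested, 10 differed between the gases, and none of these held with an estimated correlation. For the TCA cycle, 5 of 13 genes were higher adjusted over the list alone, and an exact two-sided sign-flip test over the 6 times gave p = 0.0312, the smallest it can give, with an adjusted p of 0.406 over 39 lists. Cytochrome c and complexes III and IV were 0.28 higher in CO on average (adjusted p = 0.00131, adjusted p = 0.64 with an estimated correlation), at 0.99 at 30 min and -0.30 at 120 min, and 0.13 higher without 30 min (adjusted p = 0.0472). ATP synthase was 0.24 higher (adjusted p = 0.00977, adjusted p = 0.686 with an estimated correlation, up to 0.0942 without 30 or 60 min), or 0.11 without 30 min and 0.36 without 120 min. NADH and succinate dehydrogenases were 0.19 higher (adjusted p = 0.0272, adjusted p = 0.725 with an estimated correlation, up to 0.196 without 30 or 60 min or 24 h), or 0.09 higher without 30 min. Heme proteins were 0.27 higher (adjusted p = 0.0168, adjusted p = 0.63 with an estimated correlation, 0.0633 without 30 min), with 1 member up, YHB1, and 1 down, CTT1, adjusted over the list alone. G1/S genes were 0.12 higher (adjusted p = 0.0207, adjusted p = 0.63 with an estimated correlation, 0.0664 without 45 min). Cytosolic ribosomal proteins were 0.06 higher (adjusted p = 0.0238, adjusted p = 0.883 with an estimated correlation, up to 0.995 without 15, 30 or 45 min), but -0.05 without 30 min, -0.01 without 45 min, and 0.14, 0.11 and 0.11 without 60 min, 120 min or 24 h. Lower in CO were fatty acid genes, at -0.34 (2 of 10 adjusted over the list alone), with ACC1 (YNR016C), acetyl-CoA carboxylase, at -0.73 ± 0.15 and FAS1 (YKL182W), a fatty acid synthase subunit, at -0.59 ± 0.17 being these 2, while OLE1 stood at -0.65 ± 0.23. The list test gave adjusted p = 0.00169 and adjusted p = 0.63 with an estimated correlation. The seripauperins stood at -0.30 (adjusted p = 0.000281, adjusted p = 0.63 with an estimated correlation), and general stress genes at -0.24 (5 of 17 adjusted over the list alone). As a list they had adjusted p = 0.0259 and adjusted p = 0.64 with an estimated correlation. Without 45, 60 or 120 min the list was lost (adjusted p up to 0.307), with a mean of -0.16 without 45 min. In those of the 10 lists given without such a count, 0 members passed adjusted over the list alone. The hypoxic genes, with 1 of 9 lower adjusted over the list alone, did not pass as a list, at -0.07 ± 0.06 (SD across times, adjusted p = 0.76), though lower in CO at 6 of 6 times (exact sign-flip p = 0.0312, adjusted p of 0.406, as for the TCA cycle). Heme proteins were higher in CO at 6 of 6 times, with the same sign-flip p and adjusted p. YHB1, with a difference of 1.40, was 1 of the 10 heme protein genes and carried a large part of their mean of 0.27. The list was not tested without YHB1.

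**Figure D2:**
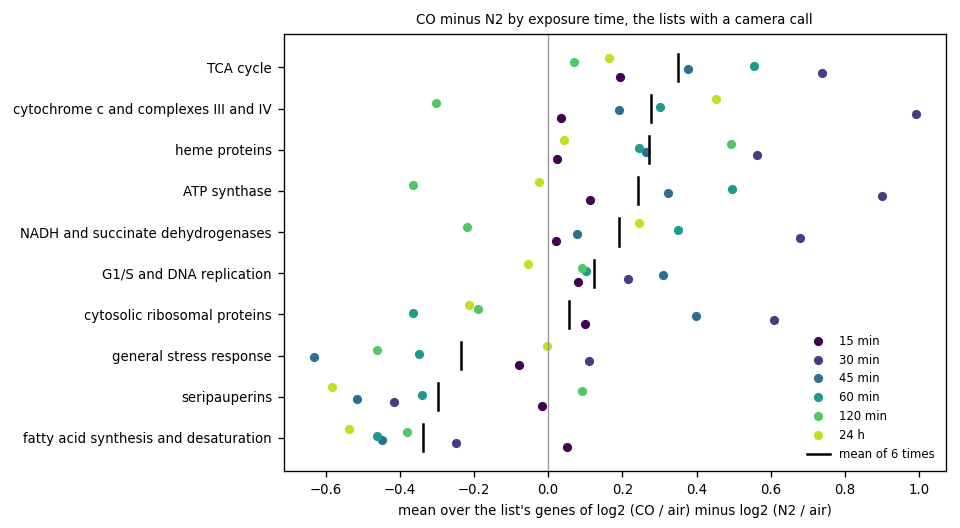
Mean log2 difference of CO minus N2 (x axis) for the 10 lists that differed between the gases, with 1 point per exposure time and a black bar at the mean of the 6 times. The TCA cycle points lie above 0 at 6 of 6 times around a mean of 0.35, while no single gene passed over all genes.

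The change from 15 and 30 min to 60 and 120 min, fitted over both gases, asks how the response develops within the first 2 h. Cytosolic ribosomal protein genes fell as a body: 92 of 120 fell and 0 rose (108 adjusted over the list alone), with a mean of -1.36, adjusted p = 6.75e-34 and adjusted p = 0.63 with an estimated correlation. RPS0A (YGR214W), a small-subunit protein, fell by 2.44 ± 0.35 (SE, n = 4 arrays against 4), with RPS1B (YML063W) at -2.33 ± 0.35. OLE1 rose by 2.05 ± 0.27 (adjusted p = 0.00593) and IZH4 (YOL101C), a membrane protein linked to zinc and sterol metabolism, by 3.66 ± 0.50, the largest rise of the named genes. Over all genes 195 rose and 527 fell, 43 and 228 of them at least 2-fold. The 15 min arrays carried the count: 0 genes were called without 15 min, 110 without the CO and 130 without the N2 array of that time, 378 without 30 min, 52 without 120 min, and 353 and 289 without the CO or the N2 array of 120 min. Every gene call named for this comparison was thus lost without 15 min (adjusted p = 0.21 for RPS0A, RPS1B, OLE1 and IZH4), though the ribosomal protein list was not (adjusted p at most 4.72e-22 with any time left out). The changes of these genes did not rest on 15 min alone. At 30 min OLE1 stood at 0.05 in CO and 0.5 in N2, against 1.09 to 2.94 at 60 and 120 min. RPS0A stood at -0.37 and -0.83, against -1.92 to -3.42. For IZH4 and RPS1B the 30 min values also lay outside those at 60 and 120 min.

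Other genes that rose were YKL107W by 2.03, GDH3 (YAL062W), a glutamate dehydrogenase, by 1.84, SPI1 and SCW4 by 1.70 each, ARE2 (YNR019W), which esterifies sterols, by 1.65, and GID10 (YGR066C), a subunit of a ubiquitin ligase, by 1.56. Others that fell were ARO10 (YDR380W), a decarboxylase of amino acid breakdown, at -2.72 ± 0.42, YRO2 at -2.34, NCA3 (YJL116C) at -2.29, RPS0B at -2.22 and RPL17B (YJL177W) at -2.17. COX5B rose by 1.32 and CYC7 by 1.23, and HEM13 fell by 0.77. Leaving out 15 min ended each of these calls, and leaving out 120 min those of YKL107W, SPI1, SCW4, ARE2, GID10, YRO2, NCA3, RPS0B, RPL17B, COX5B, CYC7 and HEM13, with adjusted p of 0.21 or more at the highest. A lost call need not mean a lost change. At 30 min in CO and N2 GDH3 stood at 0.39 and 0.68 and COX5B at -0.01 and 0.16, against 1.55 to 2.87 and 0.71 to 1.70 at 60 and 120 min. CYC7 did overlap, with 1.14 in CO at 30 min against 0.92 to 2.31 at 60 and 120 min. After quantile normalization the calls of YRO2, NCA3, CYC7 and HEM13 were lost, as were those of UTP22, RPA135, NTH1, ARO4, PHO84, XBP1, ATG14, ATG2, PAU17 and MRPL32 among list members (adjusted p = 0.0548 to 0.542). The log2 changed by more than 1.5 times for HEM13 (-0.20), RPA135, PHO84, PAU17 and MRPL32, and stayed within that for YRO2, NCA3 (-2.33), CYC7, UTP22, NTH1 (0.86), ARO4, XBP1, ATG14 and ATG2.

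Ribosome biogenesis genes fell in 22 of 76 cases (30 adjusted over the list alone; adjusted p = 2.15e-07, adjusted p = 0.64 with an estimated correlation), with UTP22 (YGR090W) at -1.42 ± 0.39, and RNA polymerase I and III genes in 5 of 18 (9 adjusted over the list alone; adjusted p = 0.00647, adjusted p = 0.64 with an estimated correlation), with RPA135 (YPR010C) at -1.20 ± 0.19. Trehalose and glycogen genes rose in 6 of 18 cases and fell in 1 (8 and 1 adjusted over the list alone), among them NTH1 (YDR001C), neutral trehalase, by 0.87 ± 0.22 and TPS1 (YBR126C), trehalose phosphate synthase, by 0.79 ± 0.15. Tested together they gave adjusted p = 0.000892 and adjusted p = 0.63 with an estimated correlation, and their mean of 0.45 was 0.28 without 15 min. In the TCA cycle 3 of 13 fell (4 adjusted over the list alone), ACO1 (YLR304C), aconitase, by 1.32 ± 0.24 and FUM1 by 1.24 ± 0.18. Their list passed at adjusted p = 0.00326 and adjusted p = 0.63 with an estimated correlation. Without 120 min the list was lost (adjusted p = 0.0719), its mean moving from -0.60 to -0.38. Ergosterol genes fell in 7 of 24 cases (9 lower and 1 higher adjusted over the list alone), with ERG5 (YMR015C) at -1.70 ± 0.32. For this list limma gave adjusted p = 0.0238 and adjusted p = 0.64 with an estimated correlation. Without 120 min the list was lost (adjusted p = 0.171), its mean moving from -0.46 to -0.29. Phosphate genes fell in 7 of 14 cases (8 adjusted over the list alone), PHO84 (YML123C), the phosphate transporter, by 1.64 ± 0.49. This call was also lost with median centring (adjusted p = 0.0515) or with genes of at least 10 arrays (adjusted p = 0.0539). The list test gave adjusted p = 0.018 and adjusted p = 0.63 with an estimated correlation. Without 60 min the list was lost (adjusted p = 0.124). Amino acid synthesis genes fell in 7 of 24 (9 adjusted over the list alone), ARO4 (YBR249C) by 1.68 ± 0.36. As a list they had adjusted p = 0.00788 and adjusted p = 0.64 with an estimated correlation. Without 60 min the list was lost (adjusted p = 0.108). General stress genes rose in 3 of 17 (4 higher and 1 lower adjusted over the list alone), XBP1 (YIL101C), a stress-induced repressor, by 1.19 ± 0.35. Tested together they gave adjusted p = 0.00655 and adjusted p = 0.63 with an estimated correlation. Without 60 min the list was lost (adjusted p = 0.0944).

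Further shifts upward were those of fatty acid genes, 2 of 10 (3 adjusted over the list alone; adjusted p = 0.0255, adjusted p = 0.64 with an estimated correlation, up to 0.116 without 30 or 120 min, mean 0.48 and 0.31 without 120 min), which included MGA2 (YIR033W), the activator of OLE1, at 1.03 ± 0.19, and of the proteasome, 1 of 31 (1 adjusted over the list alone; adjusted p = 0.01, adjusted p = 0.797 with an estimated correlation, 0.457 without 60 min, mean 0.27, or 0.10 and 0.44 without 60 or 120 min), with RPN3 (YER021W) at 0.77 ± 0.18. Autophagy genes rose in 3 of 35 cases and fell in 2 (the same counts adjusted over the list alone), with ATG14 (YBR128C) at 0.72 ± 0.17 and ATG2 (YNL242W) at -1.13 ± 0.23. Their list passed at adjusted p = 0.0353 and adjusted p = 0.63 with an estimated correlation. Without 15 or 60 min the list was lost (adjusted p up to 0.145), and its mean of 0.14 was 0.09 without 15 min. Seripauperins rose in 1 of 18 (0 adjusted over the list alone), PAU17 (YLL025W) by 0.68 ± 0.19. For this list limma gave adjusted p = 0.0125 and adjusted p = 0.753 with an estimated correlation. Without 120 min the list was lost (adjusted p = 0.327), and its mean of 0.30 was 0.10 without 120 min and 0.50 without 60 min. Mitochondrial ribosomal proteins fell in 4 of 56 cases and rose in 1 (the same adjusted over the list alone), with MRPL32 (YCR003W) at -1.03 ± 0.23. The list test gave adjusted p = 0.0168 and adjusted p = 0.797 with an estimated correlation. Without 120 min the list was lost (adjusted p = 0.092).

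**Figure D3:**
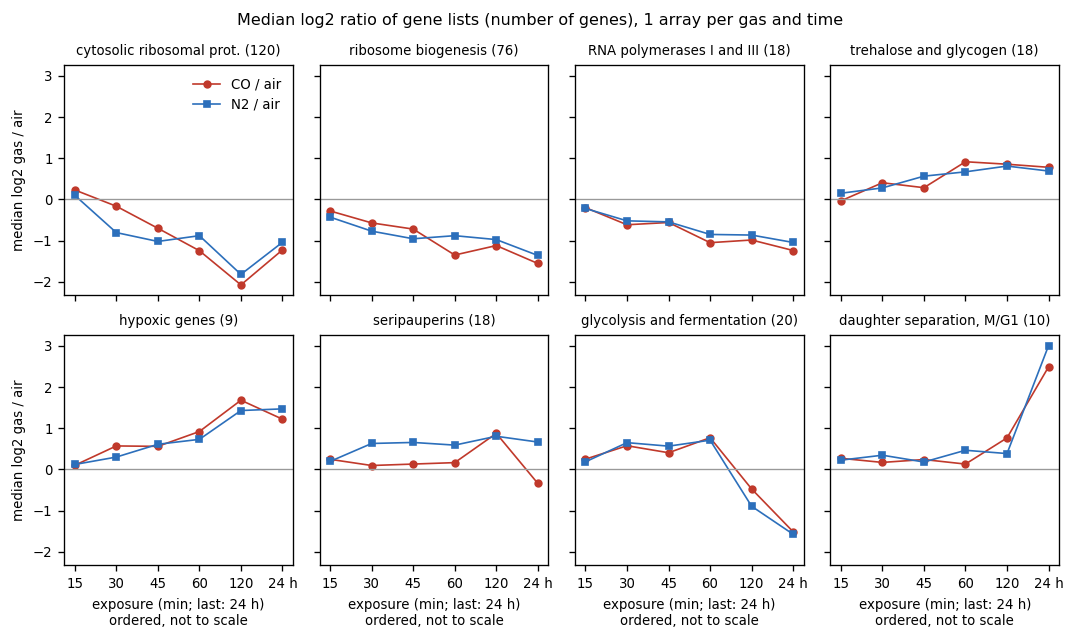
Median log2 ratio of gas over air (y axis) for 8 gene lists by exposure time (x axis), with 1 point per array for CO and for N2. The cytosolic ribosomal protein genes stand lower at 120 min than at 15 min in both gases, and the genes of daughter cell separation stand highest at 24 h.

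The 24 h arrays against the first 2 h ask what marks long exposure, when the labels describe division on acetate as reversibly arrested. PCK1 (YKR097W), the first committed enzyme of gluconeogenesis, rose by 4.56 ± 0.28 (log2, SE, n = 2 arrays against 10; adjusted p = 8.35e-07), and CWP1 (YKL096W), a cell wall mannoprotein, by 4.68 ± 0.27. The fermentation genes PDC6 (YGR087C) and PDC1 (YLR044C), pyruvate decarboxylases, changed by -3.83 ± 0.37 and -3.02 ± 0.69 from the first 2 h. ENO1 (YGR254W), an enolase, changed by -3.35 ± 0.41. PDC1 and ENO1 were already below air at 120 min, at -0.68 and -0.23 in CO and -2.01 and -0.98 in N2, while PDC6 was not. DSE2 (YHR143W), which degrades the wall between daughter and mother, rose by 4.02 ± 0.31. The call of PDC1 was lost without the N2 array of 24 h (adjusted p = 0.0539). HAP4, which activates respiratory genes, rose by 2.54 ± 0.24. Over all genes 1278 rose and 1425 fell, 704 and 708 of them at least 2-fold. Air cells had also spent 24 h on the plates, so the ratio can have changed through either channel, and with the spread of all arrays made equal by quantile normalization 386 genes were higher and 341 lower.

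The largest rises included the ORF YPR002C-A (4.88 ± 0.29) and the Ty1 ORFs YHR214C-B (4.68), YML045W (4.51), YER160C (4.23) and YBL005W-B (4.20). These Ty1 ORFs are copies of similar sequence and can share probe signal. CCW22 (YDR134C, 4.26 ± 0.22), a pseudogene close in sequence to CCW12, was also among the largest rises. The largest falls included the wall protein HSP150 (YJL159W), at -3.77, YDL218W, at -3.46, and PUN1 (YLR414C), at -3.39. SNO1 (YMR095C), of vitamin B6 synthesis, stood at -3.63 and its neighbour on the chromosome, CTF13 (YMR094W), of the kinetochore, at -3.09. Of the hypoxic genes COX5B was higher by 1.70 ± 0.23, CYC7 by 1.33 ± 0.35, HEM13 by 0.86 ± 0.21 and TIR1 by 0.76 ± 0.22, HMG1 fell by 0.96, and OLE1 stood at 0.14 ± 0.30 (adjusted p = 0.722). Against 60 and 120 min alone OLE1 was instead called lower, at -0.91 (adjusted p = 0.0479), and the calls of TIR1 and CYC7 were lost (adjusted p = 0.0818 and 0.215). Without the CO array of 24 h the calls of CYC7 and TIR1 were lost (adjusted p = 0.141 and 0.209). After quantile normalization the calls of COX5B, CYC7, TIR1 and HMG1 were lost and TIR1 stood at -0.01. With array weights those of HEM13, TIR1, CYC7 and HMG1 were lost (adjusted p = 0.0676, 0.0781, 0.0523 and 0.0685), with each log2 within 0.04 of that given.

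Amino acid synthesis genes fell in 19 of 24 cases (20 lower and 1 higher adjusted over the list alone), with LEU1 (YGL009C), of leucine synthesis, at -2.55 ± 0.23 and ARO4, of aromatic amino acids, at -2.05 ± 0.40. As a list they had adjusted p = 1.21e-05 and adjusted p = 0.63 with an estimated correlation. Ribosome biogenesis genes fell in 39 of 76 cases and rose in 1 (40 and 2 adjusted over the list alone), with ROK1 (YGL171W), an RNA helicase, at -2.22 ± 0.35 and NHP2 (YDL208W) at 1.69 ± 0.24. Tested together they gave adjusted p = 3.46e-05 and adjusted p = 0.753 with an estimated correlation. Glycolysis and fermentation genes fell in 12 of 20 cases and rose in 2 (13 and 2 adjusted over the list alone), the rises being the glucose kinases GLK1 (YCL040W) at 1.81 ± 0.36 and HXK1 (YFR053C) at 1.67 ± 0.33. Their list passed at adjusted p = 0.00208 and adjusted p = 0.753 with an estimated correlation. The list median had already turned by 120 min, from 0.77 in CO and 0.71 in N2 at 60 min to -0.475 and -0.895. At 24 h it was -1.515 and -1.575. Mitochondrial ribosomal proteins rose in 28 of 56 cases and fell in 3 (the same adjusted over the list alone), MRPL8 (YJL063C) by 2.60 ± 0.19 and MRP1 (YDR347W) by 2.09 ± 0.22. For this list limma gave adjusted p = 5.09e-05 and adjusted p = 0.64 with an estimated correlation. Daughter separation genes rose in 8 of 10 cases and fell in 1 (the same adjusted over the list alone), with DSE1 (YER124C) at 3.23 ± 0.30, EGT2 (YNL327W) at 2.99 ± 0.23 and ASH1 (YKL185W), a daughter-specific repressor, at -2.79 ± 0.19. The list test gave adjusted p = 0.000705 and adjusted p = 0.63 with an estimated correlation. Iron uptake genes rose in 9 of 23 cases and fell in 1 (the same adjusted over the list alone), with FET3 (YMR058W), the multicopper oxidase of high-affinity uptake, at 3.04 ± 0.27, FTR1 at 1.74 ± 0.23 and TIS11 (YLR136C), which degrades iron-dependent mRNAs, at -1.93 ± 0.27. As a list they had adjusted p = 0.0214 and adjusted p = 0.64 with an estimated correlation. After quantile normalization the calls of GLK1 (0.47), ARO4 (-1.12) and MRP1 (0.84) were lost (adjusted p = 0.462, 0.0713 and 0.051), and against 60 and 120 min alone that of ARO4 (-1.05, adjusted p = 0.0803). The cytosolic ribosomal protein list did not pass, with 18 of 120 lower and 4 higher (adjusted p = 0.201). The lists that passed in none of the 5 comparisons were the anaerobic mannoproteins, sterol uptake, heme synthesis, glyoxylate and gluconeogenesis, peroxisomal beta-oxidation, hexose transporters, chaperones, endoplasmic reticulum folding, histones, G2/M, meiosis, sulfur, nitrogen catabolite repressed genes, NAD synthesis and the genes the strain lacks. With 24 h left out, camera at the preset correlation did call hexose transporters higher in N2 and CO (adjusted p = 0.0282 and 0.0422). In CO against N2 it then called peroxisomal beta-oxidation higher (adjusted p = 0.0474) and sulfur genes lower (adjusted p = 0.00617). A list's median, mean and test differed in sign in 28 of the 195 list tests, 0 of them called.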

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

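In this part the tests of whether 1 time carried the TCA cycle difference, whether swaps of the gases gave its mean or one as large in any list, and whether a dye bias or a change of the air cells explained the ratios, and the splits of whole times, were chosen only after the result was seen.

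The sample values were screened in 90 groups of 6 arrays of a gas for a value far from the other 5, with a gap of more than 0.625 of the group's range. The screen found 15 values where chance gives about 1 in 20 groups, or 4.5, and 11 of them lay at 24 h; the times are a series and not repeats. The median log2 ratio of CO at 24 h was -0.18, against -0.06 to 0 at the other times. In CO at 24 h the ORFs YMR046W-A, YER138C and YJR027W stood at 3.9, 4.17 and 3.94, and HAP4 at 1.79. In N2 at 24 h YER138W-A, YMR046W-A, YER138C and YJR027W stood at 5.04, 4.89, 4.8 and 4.67, HAP4 at 2.03 and UPC2 at -1.42. Before 24 h, COX5A stood at -0.74 in CO at 120 min where its other values were 0.65 to 1.00, and LEU2, which the strain lacks, at 0.55. In N2 at 60 min 291 ORFs lacked a value, against 97 to 146 at the other times, and HIS3, also lacking in the strain in whole or part, stood at -0.91.

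Both gases moved 1426 genes away from air in a single direction. If a constant labelling bias were the whole cause, these genes would stand as far from 0 at 15 min as later, yet their median signed ratio at 15 min was 0.339 of that at 60 and 120 min (0.33 against 0.97), which argues against it for the set. For 63 of them, 4.42%, the ratio was no farther from 0 at 60 and 120 min than at 15 min, and a bias and an early lasting response cannot be told apart without a dye swap. Flipping the signs of whole times gave at most 863 and 771 genes, against counts of 2147 in N2 and 1818 in CO. Only 1 of 32 sign patterns, the real one, gave as many, the smallest share that 32 patterns allow. This argues against signs that vary at random between times. It does not exclude chance, since times of a series are not independent and a constant bias would also favour the real pattern. The drop in oxygen common to both gases remains an open biological explanation.

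Lists that differed between the gases were the TCA cycle with a mean log2 of CO minus N2 of 0.3496, cytochrome c and complexes III and IV with 0.2771, heme proteins with 0.272, ATP synthase with 0.2409, NADH and succinate dehydrogenases with 0.1921, G1/S genes with 0.1239 and cytosolic ribosomal proteins with 0.0563. The lists lower in CO were fatty acid synthesis with -0.3375, seripauperins with -0.2962 and general stress with -0.2351. Each passed a test of the difference with a preset correlation, and none with an estimated one (adjusted p = 0.63 to 0.883). For genes at an unadjusted p under 0.05, 1 of 32 swaps of the gases within times, the real one, gave as many as its 584. The other swaps gave 91 to 466. The real one's share is the smallest that 32 swaps allow, which argues against gas labels that fall at random within times. It does not exclude chance, since times of a series are not independent and no gene passed adjustment. Among 100 splits of the arrays that ignored time, 60 gave as many as the real 149; the highest, 1614, set mostly early against mostly late arrays, which points to time as the main structure of the samples.

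The TCA cycle difference had the largest mean of the 39 lists. Of 32 swaps of the gases within times, 1 gave this list a mean as large as 0.3496, with 0.3268 the highest of the others; but 5 of 32 gave some list a mean as large, up to 0.3781, so that chance cannot be excluded once the choice of the strongest list is allowed for. A smaller or later version of the same response in CO was set against random lists matched on the N2 ratio and time course. The TCA cycle list lay at percentile 100 of 10000, whose highest mean was 0.26. The random genes were drawn independently, while genes of 1 pathway can move together, and the choice of the strongest list was not allowed for. The test therefore cannot decide on this explanation. A single time was argued against by the list means of the times, which were 0.07 to 0.74 and above 0 at 6 of 6. The highest adjusted p with a time left out was 0.000146, with the preset correlation, under which alone the list passed. An effect of CO itself may be behind the difference and remains a hypothesis, as do a smaller or later response in CO, unequal normalization of the gases' arrays and chance.

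At 24 h the ratios were wider and part of the genes had turned. A wider scale of the 24 h arrays would keep each gene's sign. Of the 2703 genes called, 32.7%, 883 genes, had the opposite sign at 60 and 120 min, and 255 of those were at least 2-fold away from air at 24 h. These genes were picked by a difference that includes the 60 and 120 min values. No minimum size was asked at those times, where a gene near 0 has a sign set by noise. The share therefore cannot decide on scale. A scale alone would not turn single genes such as PDC6, which stood at 1.95 in CO and 1.21 in N2 at 60 min, and at -3.25 and -2.88 at 24 h. A change in the air cells over the day, which kept oxygen on the same medium, would give both gases the same ratios, and these correlated across genes at r = 0.832, with genes not independent replicates. A change in gas-exposed cells predicts the same, so that these explanations cannot be told apart, and whether both gases shared an air sample is not given in the sources used here.

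For 60 and 120 min against 15 and 30 min, 1 of 35 splits of the 8 arrays, the real one, gave as many as its 722 genes, and the highest of the others was 0. Most of these splits part the CO and N2 arrays of a time; those that keep whole times together are 3, too few for a share under 0.05, with 722 genes for the real one (1 of 3) and 0 the highest of the others. The 24 h comparison holds 2 arrays in 1 group and was not split in this way.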

How the results depend on the processing

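The subtraction of the 15 min ratios was chosen only after the result was seen; the other alternatives were planned. Of the counts of genes and lists under these alternatives, 102 stayed within 1.5 times the reported count and 23 moved further, and the cause was not tested except where stated. With time as a block the genes called were 3337 in N2 and 3168 in CO, where the block takes the spread between times that the gases share out of the error; LEU2, which the strain lacks, was then called in N2 (-0.29, adjusted p = 0.044). In the other direction, with the 15 min ratios subtracted, which removes a constant bias and an array, 1030 and 1107 were called. The noise of the 1 subtracted array per gas is not in that error, so these counts can be too high. With a time or array left out the counts ran from 1370 (without 45 min) to 2536 in N2 and from 1042 (without 120 min) to 2355 in CO; in CO they were also 1052 without 60 min and 1141 without the CO array of 120 min. CO against N2 gave 1 gene with arrays centred on their medians, 1 with ORFs of little change left out, 1 with time as a random block, and 0 without any replicate block, in each case of 1 gene OST2. The 24 h count was 727 after quantile normalization and 1675 with array weights, and 1917 to 2883 with a time or array left out. The count for 60 and 120 min was 151 after quantile normalization and 1377 with array weights; with a time or array left out it ran from 0 (without 15 min) to 1007, with 378 without 30 min, 52 without 120 min, 110 and 130 without the CO or N2 array of 15 min, and 353 and 289 without that of 120 min. Quantile normalization gives the wide and the narrow arrays 1 spread by construction. With an estimated correlation 0 of the 53 list calls held; median centring lost 4 and gained 0, fry lost 18 and gained 20, and leaving out 24 h lost 9 of the 47 calls outside the 24 h comparison and gained 7.

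Reversed with the 15 min ratios subtracted were URA3 in N2 (-0.69, adjusted p = 0.00934, so that a gene the strain lacks was called; its ratio was 0.67 at 15 min), MRS4 in N2 (-0.046) and RPL4B in CO (-0.002). Reversed after quantile normalization were TIR1 at 24 h (-0.0136), and RPA49 (0.15) and ATG1 (0.0334) for 60 and 120 min; against 60 and 120 min alone, OLE1 at 24 h was called lower (-0.91, adjusted p = 0.0479; 0.14 as reported). Of 274 gene calls named or drawn from the lists, 103 were lost with some time left out and 115 in no setting, and after quantile normalization 17 of 64 at 24 h and 37 of 62 for 60 and 120 min were lost. With a log2 still within 1.5 times, these losses were 0 at 24 h and 18 for 60 and 120 min; the 15 min subtraction lost 63 of 148, 17 of them so. Signal over background is not given in the sources used here, so its limits are unknown.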

Other observations

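The tests of Ty elements and of thiamine genes were chosen only after the result was seen, and so were the genes named here.

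After 24 h hexose transporter genes moved both ways, and the ATP synthase genes that were called rose. Of 17 hexose transporters and sensors 5 rose and 3 fell, and the list did not pass (adjusted p = 0.215). HXT6 (YDR343C) and HXT7 (YDR342C), near-identical high-affinity transporters, rose by 3.81 ± 0.23 and 3.69 ± 0.29, and HXT4 (YHR092C) by 3.21 ± 0.24, while HXT2 (YMR011W) fell by 2.55 ± 0.36 and HXT5 (YHR096C) by 2.17 ± 0.25. Among 19 genes of gluconeogenesis and acetate use 8 rose and 3 fell (list adjusted p = 0.215), with FBP1 (YLR377C), the gluconeogenic bisphosphatase, at 2.39 ± 0.34 and SFC1 (YJR095W), a mitochondrial succinate-fumarate carrier, at 2.23 ± 0.31. In respiration, ATP synthase genes rose in 7 of 15 cases and fell in 0, and the list missed the threshold (adjusted p = 0.0501), with ATP1 (YBL099W) at 2.48 ± 0.30. CYT1 (YOR065W), cytochrome c1, rose by 2.06 ± 0.23, and in the TCA cycle 6 of 13 rose and 2 fell (list adjusted p = 0.352), IDH1 (YNL037C) by 1.95 ± 0.30. CLN2 (YPL256C), a G1 cyclin, rose by 2.31 ± 0.18 while its list of G1/S genes had 4 higher and 8 lower of 22 (adjusted p = 0.816).

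Between the gases several genes of metabolism had 1 sign at 6 of 6 times without passing over all genes. MDH2 (YOL126C), the cytosolic malate dehydrogenase of the glyoxylate route, stood at -0.86 ± 0.14 in CO relative to N2, and ATO3 (YDR384C), a putative ammonium exporter, at -1.24 ± 0.23. LYS20 (YDL182W), homocitrate synthase, stood at 0.86 ± 0.15. Each had an adjusted p of 0.323.

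One hypothesis was that Ty retrotransposon ORFs rose as a class at 24 h. Of 27 measured 26 rose and 0 fell, with a mean of 3.10 and, adjusted over 10 tests, adjusted p = 1.15e-17, against adjusted p = 0.167 with an estimated correlation. The list had been suggested by Ty ORFs already seen among the largest changes, and copies share sequence, so that a few active elements read by many probes could give the same values. A second hypothesis was that thiamine genes moved as a class between the gases and air. It was not borne out in N2 (adjusted p = 0.656), where 2 of 14 rose and 2 fell, nor at 24 h (adjusted p = 0.255), where 3 rose and 6 fell. The members split at 24 h, with a mean of -0.80 and an SD across genes of 1.61. Among those that fell, THI4, THI5, THI11, THI12 and THI13 stood at -2.70, -2.95, -2.75, -2.86 and -2.73.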
